A study of Homo sapiens with 58 samples.

How the data were processed

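The series comprised 58 samples, and the 11 used here came from 2 established human cell lines. H1 is a human embryonic stem cell line, and HEK 293T is a transformed embryonic kidney line that takes up plasmids readily. The 8 H1 libraries were poly(A)-selected RNA-seq, per the labels' protocols. Of these, 2 came from cells given a control siRNA (siCTRL) and 2 from cells given an siRNA against WDR5 (siWDR5) for 48 h. The other libraries were single samples collected 0, 2, 8 and 10 h after release from 14 h in 5 µM STLC, an inhibitor of the mitotic kinesin Eg5 that arrests cells in mitosis. The 3 HEK 293T samples were ChIP-seq with an antibody against the Flag tag, 2 after expression of Flag-tagged CDC20 and 1 after expression of Flag-tagged WDR5. The other ChIP-seq samples and the inputs were not analysed here.

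For RNA-seq, the deposited estimated counts were one value per transcript, and the column names are those kallisto writes. The submitters' processing notes name kallisto 0.44.0, Bowtie2 2.3.4.1, deepTools 3.2.1 and hg19. The deposited TPM values, length-scaled relative abundances as the authors' quantification gave them, were used only in one alternative. The transcript annotation and the quantification settings are not given in the sources used here. Each file listed the same 180253 Ensembl transcript IDs, without gene names. The tables used here pair gene IDs, not transcript IDs, with symbols, so 0 transcript IDs were matched to a gene. The unit of analysis was therefore the transcript. The level of WDR5 in the knockdown, the 20 gene lists fixed before the data were examined and the comparisons of peaks with promoters were not analysed here.

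The authors' score for each peak was used only to rank or filter peaks within a list. The deposited peak names carry the name MACS, and there was one list per ChIP library. The submitters' processing notes name Bowtie2, without a version, and hg19/GRCh37 for these samples. The caller's version, its threshold and its use of an input are not given in the sources used here. No annotation of that build was used, so peaks are given by position only. Positions are on hg19 and counted from 1.

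Estimated counts were rounded to whole numbers. The siRNA libraries were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM normalization, the default expression filter and Benjamini-Hochberg adjustment at 0.05. Alternatives used DESeq2 1.42.0, limma 3.58.1 with voom weights, other scalings, other filters, a replicate block and each library left out in turn. For the time course, log2 ratios of TMM-normalized CPM over the 0 h library were computed with a prior count of 1, for transcripts with a mean of at least 5 CPM over the 4 libraries. No test was made there, because each time had 1 library. Intervals for single transcripts are 95% exact conditional binomial intervals and cover counting error only, and folds against a library at 0 use a floor of 3 counts per library. Median ratios of transcript lists were placed among 10000 random lists matched on expression in 20 bins. A transcript estimate was called whole when it lay within 1e-06 of an integer. Such transcripts received no fractional reads, although large estimates are printed without decimals. Correlations of libraries used 8337 transcripts with a mean of at least 20 CPM. Transcripts identical in length and in all 8 estimates were summed to 1 row for the abundance classes of the siRNA libraries, the pairs of libraries and the random lists of short transcripts. Elsewhere each of the 17516 identical transcripts, in 6825 groups, kept its own row. Trends on transcript length were fitted by lowess with a span of 0.3.

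Peak lists were compared by overlap of at least 1 bp, with Python 3.11.15 and numpy 2.4.6. The same overlap was counted after 1000 circular shifts of one list within each chromosome, with a one-sided p. Chromosome ends were taken from the last peak, and shifts ignore unmappable sequence.

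Before the data were examined, the named features were set by rule. For siWDR5 these were WDR5 and the 12 largest rises and falls past the threshold. In the time course they were the 8 largest rises and falls at each time with a mean of at least 10 CPM, and for peaks the 5 highest scores per list. With no gene names, only 2 rising and 2 falling transcripts are given. These were the ones taken by the rule at most times, and among those the ones with the largest mean ratio.

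The test was checked on simulated data for the siWDR5 comparison. These were drawn from the real means and from edgeR's estimates of the spread, for transcripts that passed its filter. The changed transcripts were drawn only from those with a mean of at least 5 CPM, so recovery among less abundant transcripts was not checked. Of 100 transcripts changed 8-fold, edgeR recovered 62, and of 100 changed 2-fold it recovered 5, with 12 false calls in all. DESeq2 recovered 90 and 40, with 217 false calls, and limma-voom 56 and 4, with 3 false calls. Labels did not state that replicates came from separate cultures, so p-values measure only the spread between these libraries. The replicate libraries were not copies of one library: chi-square per degree of freedom was 13.1 between the siCTRL libraries and 7.67 between the siWDR5 libraries, over transcripts with a summed count of at least 10.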

Results

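Transcript levels were measured by RNA-seq in H1 human embryonic stem cells in 2 experiments, an siRNA knockdown of WDR5 and a release from mitotic arrest. WDR5 is a subunit of complexes that methylate histone H3 at lysine 4, and CDC20 is an activator of the anaphase-promoting complex. The siRNA experiment had 2 siCTRL and 2 siWDR5 libraries, and the release had 1 library at each of 0, 2, 8 and 10 h. Estimated counts per library ranged from 16926640 at 0 h to 23942804 in siCTRL replicate 1. The siWDR5 libraries held 17226170 and 18520023 and siCTRL replicate 2 held 21002921. Flag ChIP-seq in HEK 293T cells gave 14000 and 24371 peaks for Flag-CDC20 replicates 1 and 2, and 4090 peaks for Flag-WDR5.

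The RNA-seq libraries were first compared with each other. Across 8337 transcripts, Pearson's r of log2 CPM was 0.975 between the siWDR5 libraries and 0.938 between the siCTRL libraries. Transcripts are not independent replicates, so these values describe the libraries only. The 2 h library had the lowest correlations, from 0.839 with siWDR5 replicate 1 to 0.872 with the 10 h library, except for 0.924 with siCTRL replicate 2. Both of these libraries held fewer reads from long transcripts. Transcripts over 5000 nt took 13.4% of the counts at 2 h and 14.9% in siCTRL replicate 2, against 17.2% in siCTRL replicate 1 and 17.5% at 0 h. The 10 h library was at 14.9% and the 8 h library at 16.8%.

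**Figure D1:**
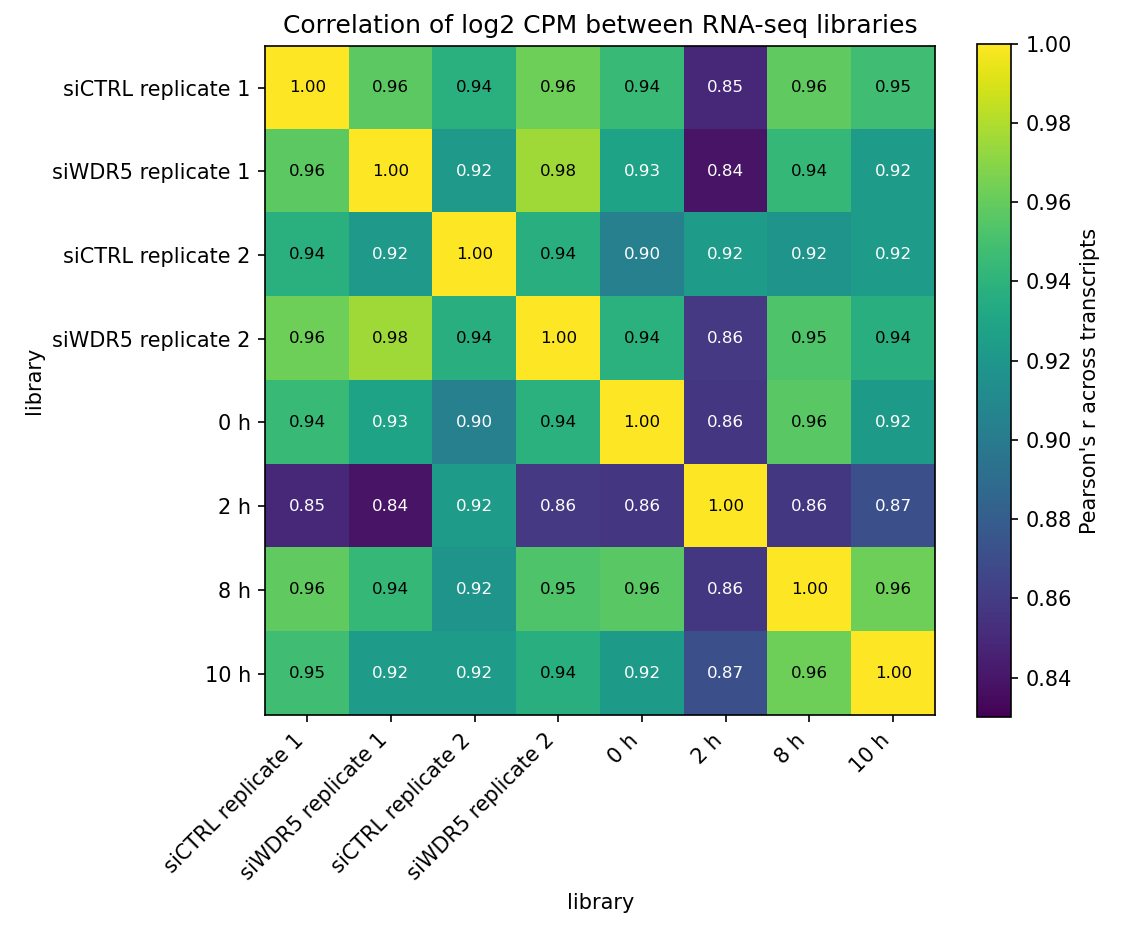
Pearson's r of log2 CPM for each pair of the 8 RNA-seq libraries, across 8337 transcripts, with libraries on both axes and colour giving r. The 2 h row is the lowest, with its highest value, 0.924, against siCTRL replicate 2.

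The siRNA experiment asks which transcripts depend on WDR5. Among abundant transcripts, those of at least 64 CPM, a subset of the short ones was lower in siWDR5. The 333 under 1000 nt did not shift as a class, with a median log2 ratio of -0.014, against 0.056 at 4000 nt or more. Of these 333 abundant transcripts under 1000 nt, 59 were lower by at least 0.5 on the log2 scale in both same-numbered pairs of libraries and 3 were higher in both. Of these 59, 4 were sums of identical transcript models. These counts were chosen after the data had been seen. Of the 333, 12 had whole estimated counts in all 4 libraries, and 0 of these 12 were lower in both pairs. The lower share was 17.7% under 1000 nt, 4.43% from 1000 to 2000 nt, 1.18% from 2000 to 4000 nt and 0.78% at 4000 nt or more. Over all 2836 abundant transcripts, 104 were lower in both pairs, 17 were higher in both and 4 went opposite ways. For the difference between replicates of one group, 10 of the same transcripts moved the same way by this size in both groups and 4 moved opposite ways. The log2 ratios of the 2 pairs, which share no library, correlated across abundant transcripts with r = 0.52, and with r = 0.28 from 20 to 64 CPM and r = 0.099 from 5 to 20 CPM. With the numbers crossed, so that each siWDR5 library was set against the siCTRL library of the other number, r was 0.36, 0.16 and 0.055. The replicate differences correlated with r = 0.26 across abundant transcripts.

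No single transcript passed edgeR's test on all transcripts. Reads that fit several transcript models are divided among them by estimation, and no gene-level test was run here, so the count of 0 is not a count of genes. Of 57971 transcripts tested with edgeR's quasi-likelihood test, 0 had an adjusted p under the threshold, and the smallest adjusted p was 0.458. At an unadjusted p under 0.05 there were 3967 transcripts, 1629 higher and 2338 lower in siWDR5, where 5% would be 2899. The direction of the excess followed which group was left with 1 library. There were 3792 higher and 2298 lower without siCTRL replicate 1, 6090 in all, and 2498 and 1717 without siCTRL replicate 2. There were 952 higher and 2684 lower without siWDR5 replicate 1, and 1052 and 3193 without siWDR5 replicate 2. Upper-quartile scaling gave 2009 higher and 1994 lower. Limma-voom called 0 and DESeq2 called 674, with 259 higher and 415 lower. Of the DESeq2 calls, 302 were at 0 in both libraries of one group, and 661 were tested by edgeR, each in the same direction. Both tools used the same counts, so this agreement is not separate support. In simulated data of this comparison DESeq2 made 217 false calls and edgeR 12. Those data followed edgeR's estimates of the spread and its filter, so 217 does not measure how many of the 674 calls were false. Among 1027 transcripts with whole estimated counts in all 4 libraries, tested alone, edgeR called 27, of which 20 were lower and 7 higher. Of the 27, 2 were under 1000 nt, a smaller share than the 349 of 1027 among those tested. This subset was chosen after seeing the data.

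The release experiment asks how transcript levels change after mitosis. The 2 h library differed most from 0 h. Of 19551 transcripts, 1152 were at least 2-fold higher at 2 h than at 0 h and 1630 at least 2-fold lower. Most were of low abundance: 935 of the rises and 1277 of the falls were at 5 to 20 CPM, 8.38% and 11.4% of that class. At 64 CPM or more, 1.23% were higher and 2.60% lower. At 8 h the counts were 617 higher and 473 lower, and at 10 h they were 753 higher and 822 lower. With 1 library per time, these differences have no replicate check. The same measure between replicate libraries gave 490 higher and 707 lower for siCTRL and 493 higher and 343 lower for siWDR5, of 19464 transcripts. Simulated unchanged libraries, drawn with the spread between the siRNA replicates, gave means of 746 higher and 767 lower at 2 h, 742 and 769 at 8 h, and 742 and 762 at 10 h. The 2 h counts were well above the simulated means in both directions, the 10 h counts were slightly above them, and the 8 h counts were below them.

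**Figure D2:**
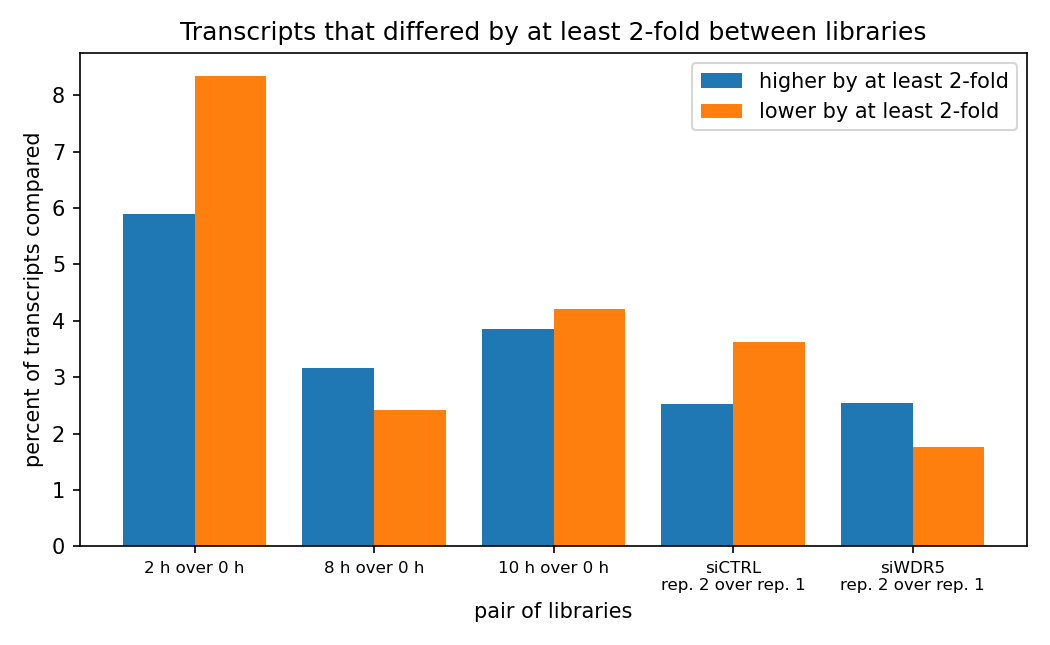
Percent of transcripts at least 2-fold higher or lower, for each release time over 0 h and for replicate 2 over replicate 1 of siCTRL and of siWDR5, 1 pair of libraries per group of bars. The 2 h library has the tallest bars, 5.89% higher and 8.34% lower, and the 8 h library lies near the replicate pairs.

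The falls at 2 h were concentrated in long transcripts. Of 991 transcripts over 8000 nt, 23.6% were at least 2-fold lower at 2 h and 3.23% at least 2-fold higher. Of 2116 transcripts under 1000 nt, 6.85% were lower and 7.28% higher. The median log2 ratio at 2 h went from 0.30 under 1000 nt to -0.52 over 8000 nt. At 10 h it went from 0.20 to -0.36, and at 8 h from 0.095 to -0.098. Across transcripts with at least 20 CPM, the rank correlation of the log2 ratio with length was -0.50 at 2 h, -0.46 at 10 h and -0.19 at 8 h. It was -0.41 for siCTRL replicate 2 over replicate 1, a pair with the same treatment, and -0.13 for the siWDR5 pair.

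**Figure D3:**
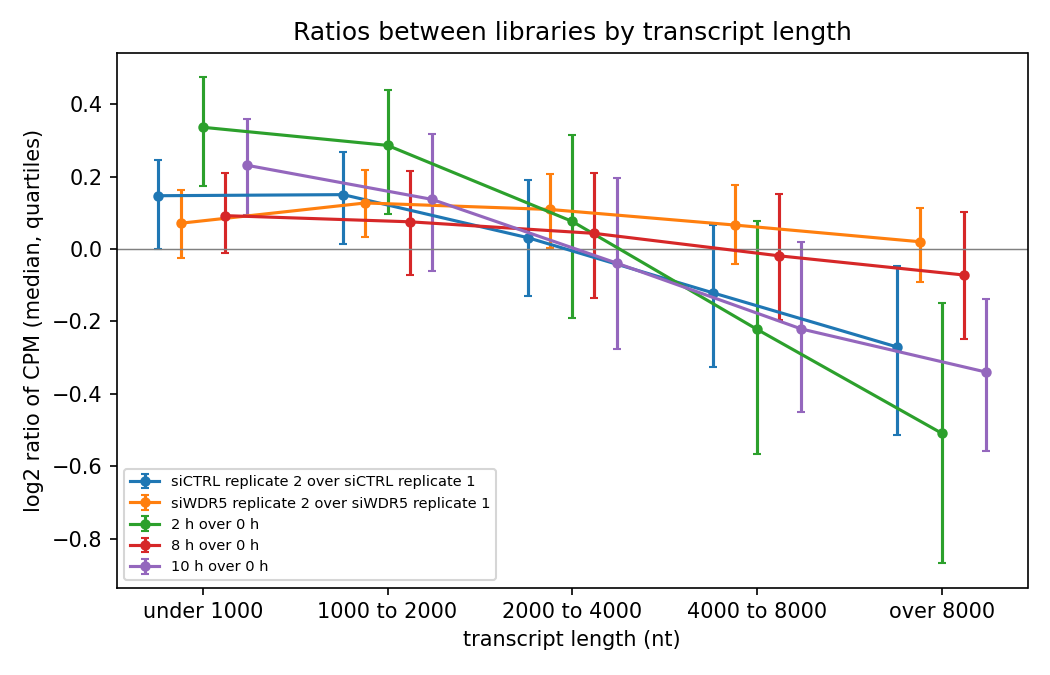
Median log2 ratio of CPM, with quartiles as bars, in 5 classes of transcript length, for 5 pairs of libraries. The ratio falls with length most for 2 h over 0 h, and also falls for siCTRL replicate 2 over replicate 1.

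Few transcripts differed from 0 h in one direction throughout. At all 3 later times 262 transcripts were at least 2-fold higher and 63 at least 2-fold lower. The shared 0 h library alone gave 188 and 104 in simulated unchanged libraries, and independent lists of these sizes would share 1.40 and 1.66. The simulated libraries differed by at least 2-fold more often than the real replicates did, so counts and covariances from the simulation may be too high. At 8 and 10 h together, 415 were higher and 205 lower, where the simulated unchanged libraries gave 311 and 219 and independent lists would share 23.8 and 19.9. The ratios at 8 and 10 h correlated across transcripts with r = 0.64, with a covariance of 0.41, against r = 0.50 and a covariance of 0.24 in the simulation. For 2 and 8 h r was 0.33 with a covariance of 0.27, against 0.51 and 0.24 in the simulation. For 2 and 10 h r was 0.42 with a covariance of 0.41, against 0.50 and 0.24. In these pairs r lay below the simulated value and the covariance above it. Part of the agreement between times may come from the shared 0 h library.

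The rule on size named 16 different transcripts among the largest rises and 24 among the largest falls. All 16 rises were at 0 counts at 0 h, and none of the rises or falls had whole estimated counts in all 4 libraries. ENST00000409321, of 735 nt, had 0 counts at 0 h and 3729 at 2 h, 142 at 8 h and 1357 at 10 h. Against the floor of 3 counts this was 964-fold, 35.9-fold and 355-fold higher. The lower 95% counting limits of the log2 ratios were 9.61, 4.85 and 8.17. Its level also differed between replicates, at 88.6 and 9.75 CPM in the siWDR5 libraries. ENST00000545646, of 3766 nt, had 0 counts at 0 h and 327, 815 and 656 later, 84.5-fold, 206-fold and 172-fold higher against the floor. The lower counting limits of its log2 ratios were 6.09, 7.39 and 7.12. This transcript was at 0.11 and 10.5 CPM in the siWDR5 libraries. ENST00000572436, of 2016 nt, had 717 counts at 0 h and 1 at 2 h, a log2 ratio of -8.81 (95% counting interval -15.2 to -7.37). Alternatives ranged from -8.98 with the length trend removed to -4.90 from the authors' TPM, with -7.21 at a prior count of 5. This transcript had 1 count at 8 h and 64 at 10 h, and it was at 20.3 and 0.24 CPM in the siCTRL libraries. ENST00000016946, of 7253 nt, had 602 counts at 0 h, 7 at 2 h, 235 at 8 h and 1 at 10 h. For 3 of these 4 transcripts, the replicate libraries of an siRNA group therefore differed severalfold.

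The 2 experiments were then set side by side, to ask whether transcripts that differed in siWDR5 also changed after release. The edgeR test gave no list. The DESeq2 list of lower transcripts, with 230 measured in the time course, had a median log2 ratio of 0.33 at 2 h, above all 10000 matched random lists, 0.06 at 8 h and 0.23 at 10 h, again above all lists. The 106 higher transcripts had medians of -0.18 at 2 h, at percentile 0.01, 0.11 at 8 h, at percentile 99.2, and -0.033 at 10 h, at percentile 33.6. When DESeq2 was run without siCTRL replicate 2, the 156 lower transcripts had medians of 0.32 at 2 h and 0.26 at 10 h, both still above all random lists. The higher list turned when that library was left out, with a median of 0.36 at 2 h, also above all random lists. The only siCTRL library was then replicate 1, whose deviations from the mean of all libraries correlated at -0.56 with those of 2 h. The turn therefore cannot be credited to siCTRL replicate 2 alone. The trend on length did not account for this turn: with it removed, the higher list had a median of -0.21 at 2 h with all 4 libraries, below all random lists, and of 0.20 without siCTRL replicate 2, above all of them. With all 4 libraries and the length trend removed, the lower list had medians of 0.12 at 2 h, at percentile 99.1, and 0.12 at 10 h, at percentile 97.5. Its median at 8 h was then -0.029, at percentile 0.01. With both changes together the lower list had medians of 0.092 at 2 h, at percentile 80.2, and 0.14 at 10 h, at percentile 91.9, while its median of -0.024 at 8 h lay below all random lists. These alternatives were added after seeing the data.

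The Flag ChIP-seq lists address where CDC20 and WDR5 bind in HEK 293T cells. Of the 4090 WDR5 peaks, 2860 (69.9%) overlapped a CDC20 replicate 1 peak and 2919 (71.4%) a CDC20 replicate 2 peak. A peak in each of the CDC20 lists was overlapped by 2574 (62.9%), whether or not those CDC20 peaks overlapped each other. Circularly shifted WDR5 peaks gave means of 0.878%, 2.60% and 0.734%. Each one-sided p was 0.001, the smallest that 1000 shifts can give. Of the CDC20 replicate 1 peaks, 83.1% overlapped replicate 2, and 40.3% of the replicate 2 peaks overlapped replicate 1, against 2.89% and 1.54% after shifts. The CDC20 replicates covered 13.7 and 52.97 Mb, with median peak widths of 808 and 1760 bp, and WDR5 covered 2.51 Mb with a median of 540 bp. No untagged control was analysed here, so the overlap does not separate the tagged proteins from sites that any Flag ChIP would recover.

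**Figure D4:**
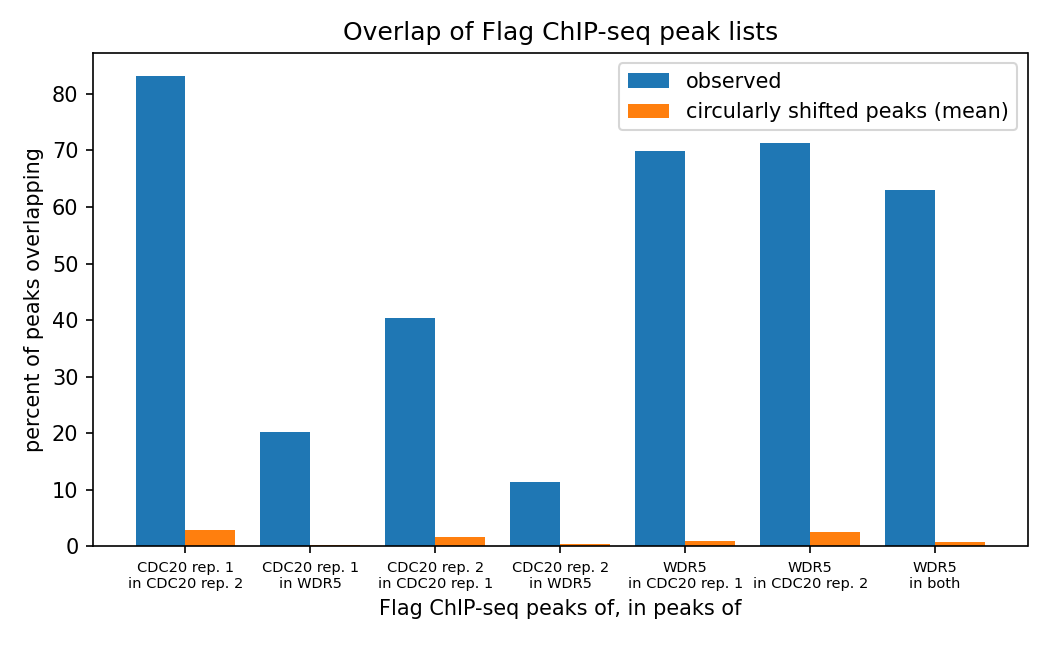
Percent of the peaks of one list that overlap a peak of another by at least 1 bp, observed and as the mean of 1000 circular shifts. Observed WDR5 overlaps are 69.9%, 71.4% and 62.9%, and shifted ones lie at or below 2.60%.

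Peaks with higher scores overlapped more often, and overlapping peaks were also wider. Median widths of overlapping and other peaks were 2453 and 1473 bp for CDC20 replicate 2 against replicate 1, and 577 and 464 bp for WDR5 against CDC20 replicate 1. Score and width were not separated. In CDC20 replicate 2, 86.4% of the highest 25% by the authors' score overlapped replicate 1, against 9.70% of the lowest 25%. In WDR5, 82.2% of the highest 25% overlapped CDC20 replicate 1, against 55.6% of the lowest 25%. The highest-scoring CDC20 replicate 1 peaks lay on chromosome 1 at 161429984 to 161442288, with a score of 3100, and at 161411310 to 161429916, with a score of 2872. Both overlapped peaks in the other lists. The next were on chromosome 10 at 77158114 to 77166359, chromosome 19 at 18387767 to 18393425 and chromosome 1 at 149810537 to 149815565. The top CDC20 replicate 2 peak lay on chromosome 17 at 79472766 to 79483106, with a score of 2098, and overlapped replicate 1 but not WDR5. It was followed by chromosome 6 at 31794144 to 31807114, chromosome 17 at 18963763 to 18976099, chromosome 10 at 77156491 to 77166783 and chromosome 17 at 43223920 to 43231374. The top 2 WDR5 peaks shared a score of 3100 and lay on chromosome 19 at 43167129 to 43167974 and chromosome 3 at 144517845 to 144518536. Both overlapped CDC20 replicate 1 but not replicate 2. The others were on chromosome 22 at 38712688 to 38714460, chromosome 21 at 9825405 to 9827858 and chromosome 1 at 45097092 to 45098283, and these 3 also overlapped CDC20 replicate 1.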

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

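The siWDR5 count of 0 transcripts held under each alternative set before the data were examined except DESeq2, which gave 674, and among the added ones except whole estimated counts, which gave 27 of 1027 tested. Leaving out each library in turn gave 0 to 0 calls, and 3636 to 6090 transcripts at an unadjusted p under 0.05. The highest came without siCTRL replicate 1. That unadjusted count was 2628 with at least 50 counts in 2 libraries and 190 for whole counts, where fewer transcripts were tested. Deviations of same-numbered libraries correlated with r = 0.062 across 19464 transcripts and r = 0.26 across abundant ones, and 2 pairs are too few to pair them. The replicate block gave 0 calls and 3229 at an unadjusted p. Of the 3 splits of the 4 libraries, the real one gave 3967 such transcripts and the highest other 1946, too few splits to weigh chance. In the time course, a mean of at least 1 CPM gave 4877 higher and 5744 lower at 2 h, 3814 and 2722 at 8 h, and 4201 and 3361 at 10 h. A mean of at least 20 CPM gave 217 and 353, 81 and 60, and 102 and 152. The authors' TPM with a pseudocount of 1 gave 607 higher at 2 h, 353 and 287 at 8 h, and 416 and 522 at 10 h. The CPM filters change how many transcripts are compared, and the shares moved as well. At 2 h, 11.7% were higher and 13.7% lower of 41845 transcripts at 1 CPM or more. The shares were 5.89% and 8.34% of 19551 in the main setting, and 2.59% and 4.21% of 8388 at 20 CPM or more. The cause of the TPM shift was not tested. With the length trend removed, counts stayed within 1.5 times. Of the siWDR5 lists, DESeq2 gave 336 transcripts measured in the time course, and 332 without siCTRL replicate 2. Overlaps of CDC20 replicate 1 with 2 were 87.2% with both lists limited to peaks at or above their own median score, 81.8% for 50% of the shorter peak and 55.6% for midpoint windows. For CDC20 replicate 2 with 1 they were 47.1% with both lists limited and 31.4% for midpoints. In the same order, WDR5 gave 62.4%, 65.8% and 60.4% with CDC20 replicate 1, 68.0%, 69.9% and 44.1% with replicate 2, and 55.8%, 59.1% and 36.1% with both. All lay above the shifted means of the 1 bp overlap. The cause was not tested. Gene lists, WDR5 itself and promoter comparisons, with their alternatives, were not run.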

Other observations

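The test of whole-count transcripts in the first pattern was chosen after the counts of transcripts seen in one pair of libraries had been looked at. The tests of depth in both patterns, of mixed RNA, of lost long transcripts and of divided reads were written after related values had been seen.

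Chromosome 6 between 27000001 and 29000000 was among the places with most CDC20 peaks. Replicate 1 had 68 and 56 peaks in its 2 windows of 1 Mb, and replicate 2 had 70 and 69. The densest window of replicate 1 was on chromosome 17 at 79000001 to 80000000, with 69 peaks. The densest WDR5 window was on chromosome 16 at 30000001 to 31000000, with 23 peaks.

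The siCTRL replicate 2 and 2 h libraries, from different experiments, deviated from the mean of all libraries in the same direction (r = 0.37 across 8337 transcripts). Their correlation stayed at 0.33 after each library's trend on length was removed, where the highest of the other 15 siRNA and time-course pairs had 0.042. This argues against a smooth length trend as the whole cause. The 2 h library's deviations correlated at -0.44 and -0.56 with those of the 8 h and siCTRL replicate 1 libraries, the closest to it in total. Deviations from a shared mean cancel out across libraries, which pushes an outlying library towards negative values, so these correlations do not decide on depth. After counts were thinned to a common total, r between siCTRL replicate 2 and 2 h was still 0.37. This argues against unequal totals alone, but thinning came after reads were divided between models, so depth at that step stays open. There were 11 transcripts seen in exactly this pair of libraries, against 2 in the next of the 28 pairs. Over 320 transcripts with whole counts in all 8 libraries r was -0.020 (bootstrap interval -0.20 to 0.16), against -0.12 in the highest other pair, so reads divided between models in the same way may account for it and this stays open. That 3 of the 6 transcripts lost at 2 h (50%, exact 95% interval 11.8% to 88.2%) were lost in siCTRL replicate 2 too goes against mixing of 2 h RNA into it, which would leave them present, but 6 transcripts are too few to exclude it, and no biological explanation was tested.

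The short abundant transcripts that were lower in siWDR5 held across libraries that did not choose them. The 63 chosen in pair 1 had a median log2 ratio of -0.74 in pair 2, with 60 lower. The 65 chosen in pair 2 had a median of -0.76 in pair 1, with 64 lower, below the lowest of 10000 random short abundant lists at -0.19. This argues against regression to the mean and, since pair 1 does not hold siCTRL replicate 2, against lost long transcripts in that library as the whole cause. These medians and the count of 59 lower in both pairs are the same evidence in 2 forms, not separate tests. Over the shallower 0 h library, the 59 lower in both pairs had medians of 0.38 at 2 h and 0.26 at 10 h. These lie in the direction that depth would give, while the 8 h median was 0.054 (quartiles -0.0012 and 0.092). At 2 h the quartiles were 0.32 and 0.43. Estimated counts were close at 2 h and 8 h, at 23420018 and 23104569, so depth alone would give close medians. For these 59 transcripts the medians argue against depth alone, but each time had 1 library, so depth is not excluded. The 762 transcripts under 1000 nt with at least 20 CPM showed the same order. Their medians were 0.34 at 2 h, 0.092 at 8 h and 0.23 at 10 h. After counts were thinned to a common total, the median in pair 2 was still -0.74. This argues against unequal totals alone, but thinning came after reads were divided between models, so depth at that step stays open. Reads divided differently between models stay open: of 12 such transcripts with whole counts in all 4 libraries 0 were lower in both pairs, which allows up to 26.5% by the exact binomial interval. A technical difference shared by both siWDR5 libraries also stays open, as does an effect of WDR5 depletion, which was not tested since WDR5 levels were not analysed here.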
